A study of Homo sapiens with 6 samples.

How the data were processed

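RNA was sequenced from exosomes, small vesicles shed by cells, that were collected from the medium of human bone marrow mesenchymal stem cells (MSC) at passage 4. Per the labels, the 3 naive libraries came from MSC grown alone and the 3 primed libraries from MSC that had shared a transwell, with a 0.4 µm membrane between the cells, with breast cancer cells for 24 h. For the primed cultures the labels add that the cancer cells were then removed and exosomes gathered over 48 h in medium with 2% exosome-depleted serum. Vesicles were isolated by ultracentrifugation, and libraries were made from total RNA with an NEB Ultra II kit, per the labels' protocols. The labels do not say whether the replicates came from separate donors or cultures, so p-values measure the spread between these samples, which may be technical.

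The authors deposited estimated counts per gene, one file per library, and 61.0% to 76.1% of the values in a library were whole numbers. Per the submitters' processing notes, STAR 2.6.1 and genome build hg38 were used; the counting tool, the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Each file listed the same 30091 gene names, and the lowest sum over the 6 libraries was 10. GENCODE 29, an annotation of the same build, matched 29760 names (98.9%) and supplied gene types, positions and exon lengths. A further 27 names had the form of dates, as spreadsheet software makes of some gene symbols, and 2 of those were repeated; they stayed in the tests and are not named here.

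Expected counts were rounded to whole numbers before any count test. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, with figures drawn in matplotlib 3.10.9. The main comparison used edgeR's quasi-likelihood test on all 6 libraries with the group as the term, TMM factors and filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM of single genes with a fold change was computed on TMM effective library sizes, and summed CPM of gene groups and CPM of single libraries on total counts. For 23 gene lists fixed before the data were examined, camera was run on log2 CPM (prior count 2) with a preset correlation of 0.01, and with an estimated correlation and limma's fry beside it. Lists with at least 5 tested genes were tested, which left 22; the osteoblast lineage list had 2 tested genes and received no test. Library composition and summed CPM were compared with two-sided exact permutation tests, whose smallest p with 3 against 3 libraries is 0.1.

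The genes named were set by a rule fixed at the same time. It took the genes past the threshold and, where a direction had fewer than 5, the 10 with the smallest unadjusted p whose libraries of one group all lay above those of the other. It also took up to 4 members of each fixed list and the 10 most abundant genes. Clone-based names, genes of the Y chromosome and XIST were passed over, and 1 gene that the rule took as lower, as well as 1 test of intestinal transcripts, is not reported here. Fold changes are given for the first part of the rule and for the picked members of the lists called without a block; genes called with the block, and the intestinal, haemoglobin, leukocyte and cancer-testis lists, were chosen after their values were seen.

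The labels number the replicates 1 to 3 in both groups. Deviations of same-numbered libraries from their group means correlated at 0.553, 0.318 and 0.373. By that measure each library correlated best, across the groups, with the library of its own number, so the numbers were taken to pair the samples. In log2 CPM itself, primed replicate 1 was closest across the groups to naive replicate 2 (0.921, against 0.872 with naive replicate 1). Naive replicate 3 was closest to primed replicate 1 (0.900, against 0.876 with primed replicate 3). The remaining libraries were closest to their own number. This pairing comes from the data and the shared numbers, as the labels do not say what a number marks. The fit with the replicate number as a block was listed as an alternative beforehand, and its values stand beside the main ones where they change a call. Other alternatives were other scaling factors, other filters, DESeq2, limma-voom with sample quality weights, robust dispersion, a fold threshold, exclusion of mitochondrial and ribosomal RNA genes, and omission of each library in turn.

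The procedure was tested on simulated counts drawn from the means, dispersions and library sizes of these samples. Without a block, edgeR recovered 2 of 93 genes changed 2-fold and 46 of 85 changed 4-fold, with 3 false calls among 14706 genes tested. With the block it recovered 38 of 97 genes changed 2-fold and 76 of 88 changed 4-fold, with 1 false call among 14701 genes. Each design was simulated from its own fit, so the blocked run took the replicate effects as given. These rates therefore cannot show a gain from the block, or its false calls, in the real libraries. The only list of 22 that camera called in simulated data was the one raised by 1 log2 unit. The simulated counts took no correlation between genes from these samples. In the real libraries camera's estimated correlation ran from -0.0251 for cell cycle arrest genes to 0.883 for mitochondrially encoded genes. The simulation therefore cannot show how often camera with the preset correlation calls unchanged lists in these samples. Total counts ran from 427102 to 1317644 per library, and Wilson 95% intervals given for shares of a single library cover counting error only, since reads without molecular identifiers are not independent molecules.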

Results

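RNA of exosomes released by naive MSC was compared with that of exosomes from MSC primed by breast cancer cells, with 3 libraries in each group. Total counts were 1317644, 1099067 and 825903 in naive replicates 1, 2 and 3, and 1171561, 1223317 and 427102 in primed replicates 1, 2 and 3. Protein-coding genes took 77.2% ± 0.976 of the counts in naive and 78.3% ± 0.747 in primed libraries (SD, n = 3 each). Primed replicate 3 was the shallowest library, with 7733 genes at 10 counts or more and 6493 genes at 0, whereas naive replicate 1 had 20725 and 60. Correlations of log2 CPM across genes ran from 0.783 to 0.884 between naive libraries, from 0.848 to 0.917 between primed libraries and from 0.714 to 0.939 across the groups, so the groups did not separate. The principal components did not separate them either.

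**Figure D1:**
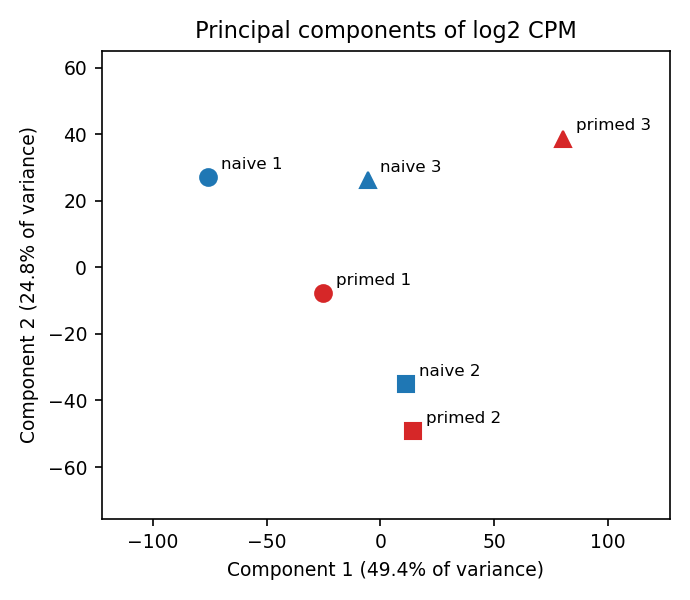
Principal components of log2 CPM, with component 1 (49.4% of the variance) on the x axis and component 2 (24.8%) on the y axis. Each point is a library, blue for naive and red for primed, with circles, squares and triangles for replicates 1, 2 and 3; naive replicate 1 and primed replicate 3 lie at opposite ends of component 1.

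The design asks which genes differ in exosomal RNA after contact with breast cancer cells. No gene passed the test between primed and naive exosomes, and more of the genes nearest to it were lower than higher in primed exosomes. Among genes whose groups did not overlap, the smallest p in the primed direction belonged to ZBED6, a transcription factor gene derived from a transposon, at 121 ± 25.1 CPM in primed against 58.8 ± 8.99 in naive libraries (SD, n = 3 each). In the other direction stood TMEM108, at 3.81 ± 1.39 CPM in primed against 19.4 ± 9.53 in naive libraries, and EDNRB, an endothelin receptor gene, at 3.81 ± 1.86 against 17.6 ± 3.66. In single primed libraries these genes were at 1.73 to 5.32 CPM, near the counting floor, so their primed levels rest on few reads. Genes of the proteasome, of oxidative phosphorylation and of the ribosome lay mostly above 0 as groups, each by a small amount. None of these lists was called by camera with an estimated correlation (adjusted p = 0.835 each).

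Of 15333 genes tested with edgeR, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.978. An unadjusted p under 0.05 was reached by 340 genes, 65 higher and 275 lower in primed exosomes, against 766.65 expected by chance. DESeq2, run without that filter on 30073 genes, also called 0, with 364 at an unadjusted p under 0.05. Limma-voom, on the same 15333 genes as edgeR, called 0 with 1275. The groups did not overlap in 1084 genes (7.07%), 469 higher and 615 lower in primed libraries. Chance gives 10% for unpaired libraries, and the pairing taken above would lower that share.

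With the replicate number as a block, edgeR called 71 genes, 9 higher and 62 lower in primed exosomes, and 1569 genes had an unadjusted p under 0.05, 494 higher and 1075 lower. The blocked p-values are those of a normal distribution for the fold change over its SE. They thus rest on a spread shared across genes, with almost no weight on the gene's own spread between pairs. The count of 71 genes depended on the tool and on the libraries. With the same block DESeq2 called 0 genes, and 395 of the 30091 it tested had an unadjusted p under 0.05. Limma-voom called 114 with 60 shared, and edgeR with library size alone 7, all shared. Without both replicate 1 libraries the blocked fit called 2 genes, none of them among the 71.

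The 10 named genes higher in primed libraries had log2 fold changes of 0.73 to 2.98 and unadjusted p from 0.00208 to 0.0247 in edgeR, with adjusted p of 0.978 each. ZBED6 (chromosome 1, 203795714 to 203854999, hg38) had a log2 fold change of 1.05 ± 0.27 (SE), and 1.04 ± 0.24 with the block, where its adjusted p was 0.0148. RAB4B-EGLN2 (chromosome 19, 40778242 to 40808418) had 2.98 ± 0.77, and 3.08 ± 0.50 with the block (adjusted p = 1.68e-05). Its naive levels were near the counting floor, at 1.56, 9.78 and 0 CPM in naive replicates 1, 2 and 3. BCL2L2-PABPN1 (chromosome 14, 23306835 to 23325369) had 2.05 ± 0.54, and 2.01 ± 0.49 with the block (adjusted p = 0.017). RAB4B-EGLN2 and BCL2L2-PABPN1 are read-through genes whose exons overlap those of their parts, and ZBED6 overlaps ZC3H11A, so their counts depend on how shared reads were assigned and are uncertain. ENDOG, which encodes a mitochondrial endonuclease, had 31.3 ± 1.83 CPM in primed against 14.9 ± 2.17 in naive libraries, a log2 fold change of 1.08 ± 0.37. CSNK2A2, a catalytic subunit of casein kinase 2, had 0.73 ± 0.27, PIAS3, an inhibitor of STAT3, 0.81 ± 0.31, and WDR46 0.98 ± 0.38. CLP1, an RNA kinase gene that overlaps another gene, had 1.08 ± 0.39. The pseudogenes EIF4BP9 and PRDX2P1, which can take reads of their parent genes, had 1.27 ± 0.45 and 1.02 ± 0.37. None of the last 7 passed with the block.

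The 9 named genes lower in primed libraries had means of 15.9 to 46.3 CPM in naive libraries. TMEM108 (chromosome 3, 133038391 to 133397792) fell by 2.42 on the log2 scale with the block (SE 0.60, adjusted p = 0.0193). EDNRB (chromosome 13, 77895481 to 77975529) fell by 2.35 (SE 0.61, adjusted p = 0.0348), and CBS (chromosome 21, 43053191 to 43076943), the gene of cystathionine beta-synthase, fell by 1.93 (SE 0.52, adjusted p = 0.0469). In primed replicate 3, with 427102 total counts, TMEM108, EDNRB and CBS were each at 5.32 CPM, which is only a few reads. CECR2, ACSS3 and SLC24A4 passed with the block at log2 fold changes of -1.80, -1.74 and -1.76, with adjusted p of 0.0317, 0.0152 and 0.0199. TSHZ3, PDLIM3 and VSTM2A, at -1.42, -1.01 and -2.12 with the block, did not pass. VSTM2A overlaps another gene on the same strand. In naive replicates 2 and 3, 7 of these 9 genes, and 4 of the 10 higher genes, had fewer than 3 times the counts per kilobase of olfactory receptor genes. None of these 19 genes changed sign in an alternative that tested it, which their choice for non-overlapping groups nearly ensures.

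**Figure D2:**
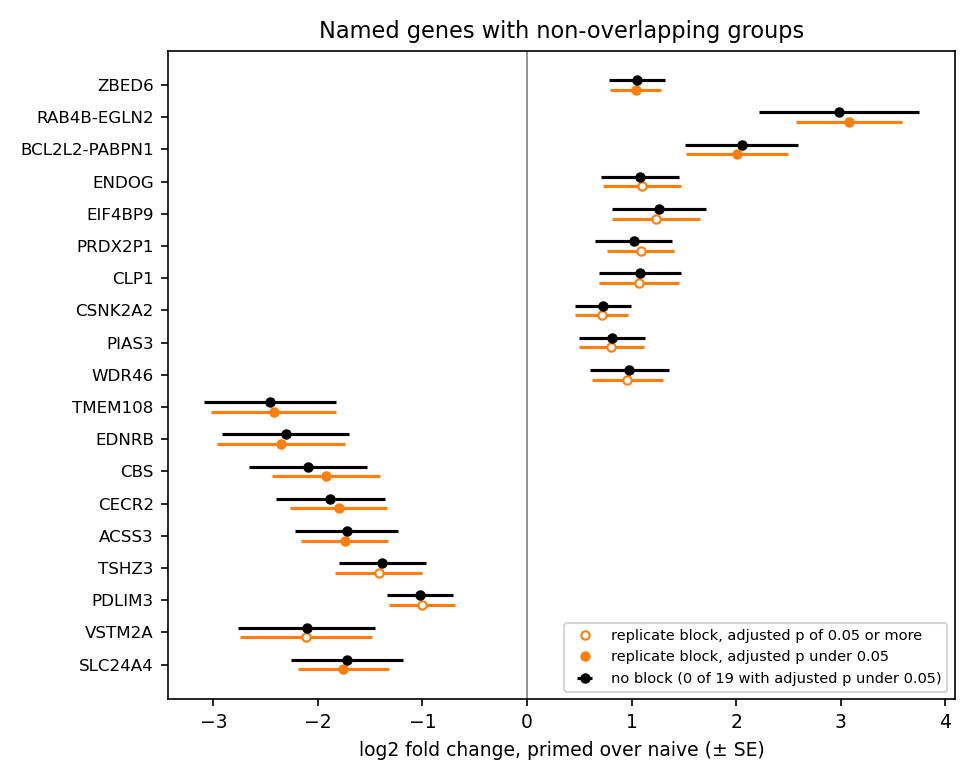
Log2 fold change of primed over naive (x axis) for the 19 named genes (y axis), with bars of 1 SE. Black points are the edgeR fit without a block, in which 0 of 19 passed, and orange points the fit with the replicate block, filled for the 9 with an adjusted p under 0.05.

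Other genes called with the block, chosen after their values were seen, included the cancer-testis gene MAGEA6 (1.53 ± 0.34, adjusted p = 0.0121), the coagulation factor gene F3 (0.94 ± 0.24, adjusted p = 0.0348), the heat shock gene HSPA1B (0.94 ± 0.24, adjusted p = 0.0348) and the fatty acid synthase gene FASN (0.90 ± 0.24, adjusted p = 0.0349). The read-through genes TMEM189-UBE2V1 and C7orf55-LUC7L2 were the remaining 2 of the 9 higher genes, at 1.66 and 1.24. MAGEA6 and HSPA1B have near-identical copies and are uncertain. The long non-coding RNA KCNQ1OT1 fell by 0.94. Among the lower genes were genes of white blood cells, with log2 fold changes of -1.88 for CYBB, -1.82 for FCGR2B, -1.47 for IL7R, -1.66 for ITGAM, -1.38 for CD14 and -1.19 for PTPRC, and CXCL8 of the fixed inflammatory list, at -1.93. Those 7 were highest in naive replicate 1, and without that library their unblocked fold changes turned positive, to 1.93 for CYBB and 1.38 for CD14, with primed replicate 1 kept. With both replicate 1 libraries left out only IL7R and PTPRC were tested, and they stayed below 0, at -0.66 and -0.24.

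The fixed lists ask whether genes of a pathway or cell type moved together. With the preset correlation, camera called 5 of 22 lists, all higher in primed exosomes. The proteasome, which degrades tagged proteins, had 28 of 30 tested genes above 0, a median log2 fold change of 0.31 and an adjusted p of 8.6e-06. Nuclear-encoded oxidative phosphorylation had 31 of 37 above 0 (median 0.26, adjusted p = 9.2e-04), ribosomal proteins 60 of 76 (median 0.14, adjusted p = 0.0106), cell cycle progression 31 of 34 (median 0.37, adjusted p = 0.0146) and exosome machinery 22 of 28 (median 0.18, adjusted p = 0.0257). In each of the 5 lists 0 members passed over all genes and 0 adjusted over the list alone. With an estimated correlation none of the 5 held (adjusted p = 0.835 each), and fry called 0 lists with 1 at an unadjusted p under 0.05.

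In the proteasome list, PSMD2 had a log2 fold change of 0.44 ± 0.31 (SE), PSMB1 0.37 ± 0.27, PSMB4 0.33 ± 0.28 and PSMD1 0.40 ± 0.28. The ATP synthase genes ATP5F1B and ATP5F1A had 0.24 ± 0.38 and 0.22 ± 0.35, UQCRC1 of complex III 0.26 ± 0.30 and COX5A of complex IV 0.30 ± 0.33. RPL5 had 0.32 ± 0.33, RPS14 0.14 ± 0.31, RPS6 0.12 ± 0.30 and RPS3 0.14 ± 0.29. The replication helicase gene MCM7 had 0.72 ± 0.48, CENPF 0.73 ± 0.53, MKI67 0.42 ± 0.61 and TOP2A 0.31 ± 0.42. The vesicle cargo genes HSPA8, HSP90AA1, YBX1 and HNRNPA2B1 had 0.31 ± 0.36, 0.40 ± 0.36, 0.28 ± 0.36 and 0.18 ± 0.36. Naive replicate 1 had the lowest summed proteasome level, 2369 CPM against 3361 to 4139 in the other 5 libraries. Sums of oxidative phosphorylation genes were 4299, 7064 and 6472 CPM in naive and 6065, 6876 and 7788 CPM in primed replicates 1, 2 and 3. Those of exosome machinery were 4710, 7787 and 7150 CPM in naive and 7052, 7837 and 7938 CPM in primed replicates 1, 2 and 3. Both were lowest in naive replicate 1 and highest in primed replicate 3, as were those of the 18 intestinal genes given below (6644 and 15075 CPM). Cell cycle sums were 1379, 2284 and 1014 CPM in naive and 2176, 2876 and 903 CPM in primed libraries. They were lowest in primed replicate 3, next in naive replicate 3 and highest in primed replicate 2, as were those of 6 cancer-testis genes (9.37, 21.7 and 316 CPM). Without naive replicate 1 the adjusted p was 0.0731 for the proteasome, 0.131 for oxidative phosphorylation, 0.0731 for the cell cycle and 0.676 for exosome machinery, and 3.9e-04 for ribosomal proteins. Without both replicate 1 libraries the proteasome and ribosomal protein lists were still called (adjusted p = 0.0156 and 0.0142). Oxidative phosphorylation (0.0686), cell cycle and exosome machinery (0.670 each) were not. The cell cycle call was also lost without naive replicate 3 (0.296), primed replicate 1 (0.101) or primed replicate 2 (0.688), and that of exosome machinery without primed replicate 3 (0.253).

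With the block camera called 8 lists, adding stromal matrix genes as higher (adjusted p = 0.0285) and blood cell genes and mitochondrially encoded genes as lower (adjusted p = 0.00914 and 0.0136). The stromal matrix sum differed, primed minus naive, by 1180, 409 and -1682 CPM in pairs 1, 2 and 3. Without the block its direction turned to lower when naive replicate 1, naive replicate 2 or primed replicate 3 was omitted. With an estimated correlation the block left 0 lists (adjusted p = 0.640 for each of the 8). Over all genes, 3 blood cell genes passed with the block and 10 when adjusted over the list alone, all lower. Adjusted over the list alone, 3 cell cycle genes were higher, and 3 inflammatory genes, 2 nuclear long non-coding RNAs, 1 endothelial gene and 1 cell cycle arrest gene were lower. FASN was the 1 adipocyte lineage gene that passed, over all genes and adjusted over the list alone. Without naive replicate 1, with primed replicate 1 kept, the blood cell list turned to higher (adjusted p = 0.0396), and without both replicate 1 libraries it was not called (adjusted p = 0.796).

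The remaining lists were not called without a block. Stromal matrix genes, which mark the cell of origin, were highest in both replicate 3 libraries, with sums of 3401, 2879 and 13920 CPM in naive and 4581, 3288 and 12238 CPM in primed replicates 1, 2 and 3. COL1A2 was at 242, 229 and 1363 CPM in naive and 372, 190 and 1257 CPM in primed libraries. Genes of the MSC surface summed to 1808 ± 654 CPM in naive and 1925 ± 652 CPM in primed libraries (SD, n = 3 each, exact p = 0.5). In pairs 1, 2 and 3 that sum was higher in the primed library by 124, 115 and 115 CPM. The exact sign-flip p over pairs was 0.25, the smallest that 3 pairs allow, in a test chosen after the data were seen. Of the 23 fixed lists, 7 sums were higher and 2 lower in all 3 pairs, where chance gives 25% of lists in either direction. Genes of carcinoma-associated fibroblast activation had 10 of 17 above 0 (camera adjusted p = 0.483), of the TGF-beta response 14 of 22 (0.194), of the interferon response 14 of 24 (0.923), of the Wnt pathway and stemness 14 of 24 (0.336), of hypoxia and glycolysis 16 of 24 (0.201) and of the unfolded protein response 14 of 22 (0.266). Inflammatory genes had 8 of 14 below 0 (0.266), endothelial genes 9 of 10 (0.119), nuclear long non-coding RNAs 8 of 13 (0.483), structured non-coding RNAs 9 of 11 (0.266) and cell cycle arrest genes 10 of 20 (0.993). Adipocyte lineage genes had 5 of 10 above 0 (0.449). Their sum was higher in every primed library, at 582, 634 and 576 CPM against 542, 537 and 519 CPM in naive replicates 1, 2 and 3 (exact p = 0.1). Without FASN, left out after its call was seen, it was 432 ± 25.5 against 442 ± 33.0 CPM (SD, n = 3 each, exact p = 0.7). The median, the mean and the camera direction differed in sign for the stromal matrix, fibroblast activation, MSC surface, interferon and cell cycle arrest lists.

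Haemoglobin and white blood cell transcripts stood apart in the libraries numbered 1. HBA1, HBA2 and HBB together took 1.12% of the counts of naive replicate 1 (Wilson 95% interval 1.10 to 1.14) and 0.265% of primed replicate 1 (0.255 to 0.274), against 0.00351% to 0.00539% in the other 4 libraries. The 12 white blood cell genes summed to 3966 CPM in naive replicate 1 and 1610 CPM in primed replicate 1, against 723 to 862 CPM in the others. HBA1 and HBA2 are near-identical, so the division between them is uncertain.

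**Figure D3:**
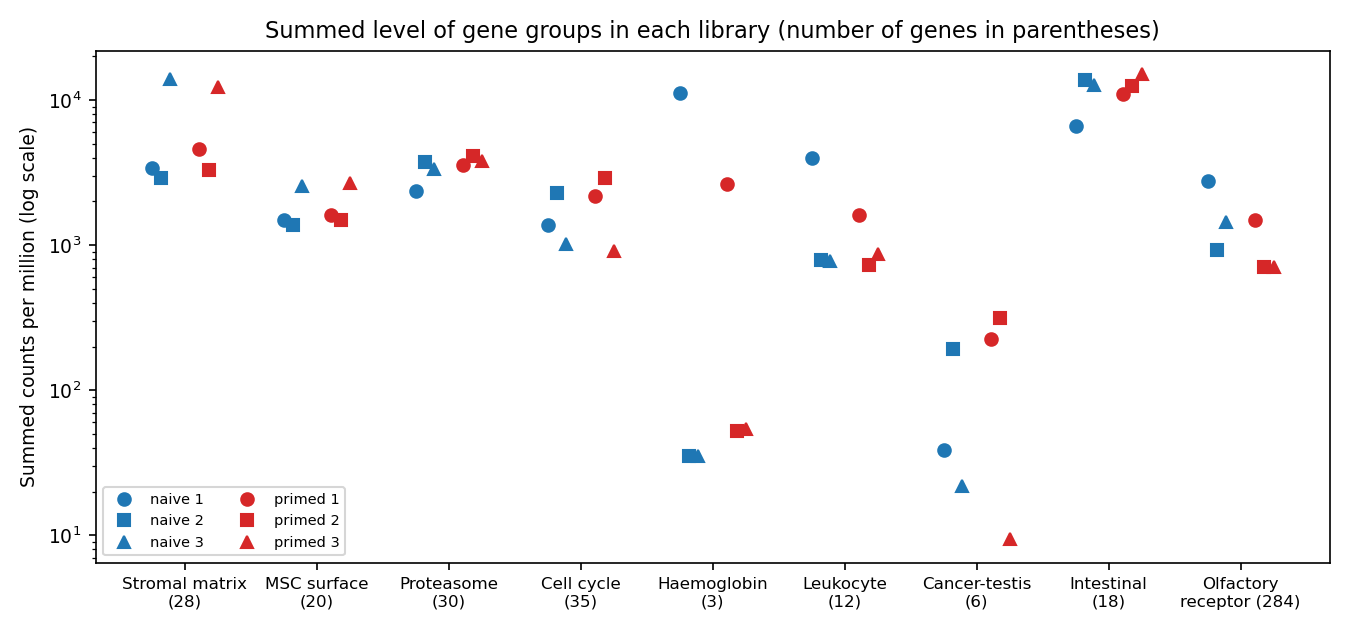
Summed CPM (y axis, log scale) of 9 gene groups (x axis), with each point a library, blue for naive and red for primed and circles, squares and triangles for replicates 1, 2 and 3. Haemoglobin transcripts reached 11176 CPM in naive replicate 1 and 2645 CPM in primed replicate 1, and 35.1 to 53.9 CPM in the other libraries.

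Breast epithelial genes were followed because breast cancer cells had been present beside the primed MSC. The 27 genes found in the files, of 28 listed, summed to 3724 ± 1011 CPM in naive and 4226 ± 473 CPM in primed libraries (SD, n = 3 each), a difference within the spread (two-sided exact permutation p = 0.7). Without naive replicate 1 the primed libraries were lower by a difference of -78.0 CPM. Of 23 tested genes 19 lay above 0, and the list was not called (camera adjusted p = 0.0955, and 0.835 with an estimated correlation). Without a filter camera called it higher (adjusted p = 0.0297). Without naive replicate 1 camera's direction turned to lower (adjusted p = 0.918). KRT8 had 528, 1062 and 946 CPM in naive and 875, 972 and 987 CPM in primed replicates 1, 2 and 3, and EPCAM 85.8, 177 and 143 CPM against 150, 180 and 187 CPM. These epithelial genes are also expressed in intestine. A set of 18 intestinal genes summed to 11019 ± 3837 CPM in naive and 12878 ± 2057 CPM in primed libraries (exact permutation p = 0.7), and the breast epithelial sums ranked the 6 libraries in the same order as the intestinal sums. Those 18 were chosen after their values were seen. Of 14 other genes abundant in small intestine, listed before theirs were looked at, 8 were found in the files and summed to 1610 ± 540 CPM in naive and 1832 ± 165 CPM in primed libraries (SD, n = 3 each, exact permutation p = 0.7). Their levels were uneven. Means over the 6 libraries were 691 CPM for FCGBP, 405 for MTTP, 277 for ITLN1 and 213 for RBP2. They were 71.6 CPM for REG1A, 31.5 for OLFM4, 27.3 for SST and 4.78 for REG1B.

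The make-up of the libraries was compared over 14 measures (two-sided exact permutation p from 0.1 to 0.9, adjusted p = 0.9 each), and with 3 against 3 libraries none could have passed. Ribosomal protein genes took 2.43% ± 0.153 of the counts in naive and 2.64% ± 0.0506 in primed libraries (SD, n = 3 each), with every primed library above every naive one and an exact p of 0.1, the smallest possible. Mitochondrial genes took 1.41% ± 0.638 and 1.22% ± 0.451, structured non-coding RNAs 2.36% ± 1.81 and 1.55% ± 0.507, replication histone genes 0.222% ± 0.105 and 0.204% ± 0.079, and snoRNAs 0.0978% ± 0.0623 and 0.0868% ± 0.054. The 10 most abundant genes took 5.01% ± 1.22 and 4.49% ± 0.141. Olfactory receptor genes, which few tissues express, summed to 1714 ± 942 CPM in naive and 965 ± 450 CPM in primed libraries (exact p = 0.3).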

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

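Fits that leave out both replicate 1 libraries, and blocked fits with DESeq2, limma-voom, library size alone or an estimated correlation, and sign-flip tests of the pairs were chosen after the data were seen. A result counted as reversed when its direction changed, whether or not it had passed a test. The count of 0 genes was the same under every alternative without a block, including each omitted library. With the replicate block it was 71, with limma-voom and the block 114, with library size alone and the block 7, and with the block and no replicate 1 libraries 2; the cause was not tested. The block changed no call other than those given in the report. The count of lists was 0 with an estimated correlation, 0 with fry, 8 with the replicate block, 11 without a filter, 2 without both replicate 1 libraries, and 0 with the block and an estimated correlation; omitting a library gave 2 to 14. The lowest count came without naive replicate 1 and the highest without naive replicate 3.

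Of 117 genes the rule picked, 62 changed sign in at least 1 alternative, among them COL1A2, ACTA2 and ITGB1; members of lists not called without a block, where most of these sign changes fell, have no fold change in the report unless the block called them. Of the 53 genes with a fold change in the report, 15 changed sign. With the stricter filter RPS14 was at -0.036, RPS6 at -0.0745 and RPS3 at -0.0558, and with limma-voom IL7R was at 0.28. Omitting a library gave log2 fold changes of -4.79 to 1.93 for CYBB, -3.11 to 0.064 for FCGR2B, -5.85 to 0.50 for CXCL8, -3.54 to 1.44 for IL7R, -2.45 to 0.85 for PTPRC, -3.20 to 0.78 for ITGAM and -3.34 to 1.38 for CD14. It gave -0.0636 to 0.41 for HNRNPA2B1, -0.0049 to 0.49 for ATP5F1B, -0.0124 to 0.41 for ATP5F1A, -0.11 to 0.73 for TOP2A and -0.37 to 1.21 for MKI67.

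List directions reversed with fry for interferon and cell cycle arrest (adjusted p = 0.892 each), with library size alone for cell cycle arrest (0.879) and without a filter for nuclear long non-coding RNAs (0.808). Without both replicate 1 libraries they reversed for fibroblast activation (0.989), blood cell (0.796), structured RNA (0.949), nuclear RNA (0.926), Wnt (0.926) and unfolded protein lists (0.879). The next 12 lists reversed direction in at least 1 omission of a library. Of those reversals only the blood cell list without naive replicate 1 had an adjusted p under 0.05 (0.0396), and the other values under 0.05 below belong to omissions that kept the direction. Over all 6 omissions adjusted p ran from 2.1e-10 to 0.939 for stromal matrix, 0.00209 to 0.847 for fibroblast activation, 0.0112 to 0.918 for breast epithelial, 6.3e-04 to 0.688 for blood cell, 0.0023 to 0.571 for structured RNA, 0.149 to 0.780 for nuclear RNA and 0.0439 to 0.993 for inflammatory genes. It ran from 0.0228 to 0.665 for the unfolded protein response, 8.9e-05 to 0.846 for mitochondrially encoded genes, 0.187 to 0.837 for interferon, 0.0084 to 0.840 for MSC surface and 0.147 to 0.952 for adipocyte genes. The differences in share reversed without both replicate 1 libraries for replication histones (0.013%), snoRNAs (0.00417%) and the 10 most abundant genes (0.0995%). Omitting a library gave -0.525 to 0.109% for mitochondrial genes, -0.0684 to 0.0364% for histones, -1.35 to 0.232% for structured RNAs, -0.0421 to 0.0203% for snoRNAs, -0.917 to 0.177% for the top 10, and -78.0 to 848 CPM for breast epithelial genes. Exact sign-flip tests of the pairs gave p from 0.25 to 1 for the shares and 0.5 for breast epithelial genes. In simulated data 2-fold changes were rarely recovered without the block (2.15%). With the block 39.2% were recovered, in counts simulated from the blocked fit itself. The rates come from different simulated data and cannot show a gain from the block in these libraries.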

Other observations

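The tests of another mammal's intestinal reads, of background reads and of naive replicate 1 as the source of the genes lower with the block were chosen after the result was seen, as were the added marker lists. Cancer-testis genes, which most normal adult tissues other than testis do not express, were low in both replicate 3 libraries. The 6 genes MAGEA2, MAGEA3, MAGEA6, MAGEA12, MAGEB2 and PASD1 summed to 38.7, 193 and 21.7 CPM in naive and 227, 316 and 9.37 CPM in primed replicates 1, 2 and 3 (two-sided exact permutation p = 0.4). They took 0.0193% of the counts of naive replicate 2 (Wilson 95% interval 0.0169 to 0.0221), where the labels name no cancer cells, and 0.0227% of primed replicate 1 (0.0201 to 0.0256). MAGEA3 and MAGEA6 are near-identical, so the division between them is uncertain.

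Some transcripts of intestinal epithelium were abundant in all 6 libraries. APOA1 had a mean of 1435 CPM, ZG16 1230 CPM and MGAM 1136 CPM, and over the 18 intestinal genes log2 CPM of any pair of libraries correlated across genes at 0.985 to 0.998. RNA of human intestinal cells stays open. Reads of another mammal's intestine aligned to the human genome are a candidate explanation, since MTCO1P53, a nuclear copy of a mitochondrial gene, followed the intestinal sum with a Pearson r of 0.993 (exact permutation p = 0.00139, adjusted 0.00278) and a Spearman rho of 1 (p = 0.00278, adjusted 0.00556; n = 6), and r was 0.953 without naive replicate 1 and primed replicate 3, while MT-ND4 had r = -0.485 (exact p = 0.336) and rho = -0.429 (exact p = 0.419). Processed pseudogenes as a class ranked the 6 libraries in the same order as the intestinal sum, from 9.91% of counts to 16.9%. The breast epithelial sums did so too, so this order was not particular to MTCO1P53. The design names no intestinal sample, so no biological explanation was tested.

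Blood cell transcripts were highest in naive replicate 1 and next in primed replicate 1. Separate blood cells in each culture with red and white cells in different proportions are argued against, since the excess in primed over naive replicate 1 was 0.233 for haemoglobin and 0.273 for white blood cell genes, a quotient of 0.852 within the bound of 1.5 set beforehand. Part of the naive replicate 1 material or reads in the primed replicate 1 library may be the source. The comparison used 1524 genes outside the haemoglobin and fixed blood cell lists, chosen for the largest difference between naive replicate 1 and primed replicate 2. Over these the slope was 0.322, within the same bound of 1.5 of the haemoglobin ratio. White blood cell genes outside those lists, such as CYBB and IL7R, were not excluded, so the slope is not independent of the blood ratios. The same slope was 3.7e-04 for naive replicate 2, 0.089 for naive replicate 3 and -0.250 for primed replicate 3. A share of naive replicate 1 cannot be negative, so a slope of that size arose without one. The slope of 0.322 therefore cannot decide whether material or reads were shared. Blood cells in similar proportions in both cultures, from a shared donor or present separately in each, would give the same values. Both stay open, since the ratios bear only on different proportions and come from a single pair of libraries.

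Of the genes called with the block, 62 were lower in primed exosomes. Blood cell transcripts of naive replicate 1 alone are argued against as the whole source, since 38.7% of the 62 (24 genes) had a naive replicate 1 level above 4 times both other naive libraries; this test replaced another after its result was seen, the median log2 fold over pairs 2 and 3, which was -1.18 and argued the same way but is biased because the genes were picked as lower. A higher background of reads spread over untranscribed genes in the naive libraries may contribute, since 85.5% of the 62 lay under 3 times the olfactory receptor density in naive replicates 2 and 3, against 40.5% of all tested genes. That contrast is not independent of blood cell transcripts in naive replicate 1. The 24 genes above would tend to lie low in naive replicates 2 and 3 without such a background. Olfactory receptor genes were lower in the primed library of each pair, by log2 differences of -0.89, -0.40 and -1.04. An effect of priming on these genes remains untested against this.

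Splits of the 6 libraries were too few to give a share under 0.05. Without the block the real split gave 0 genes, which every split equals or exceeds, so that count tests nothing, and the highest other split gave 2. With the block the real split gave 71 genes, against at most 1 in the other 3 of the 4 splits that part every pair. For the lists, among the same 4 splits, a comparison chosen after the data were seen, the real one gave 5 and the highest other 4 without the block, and 8 and 7 with it. The 6 splits that keep pairs together gave 5 to 16 lists without the block, so that 7 of all 10 gave at least 5. The highest counts, 12 in 1 split and 16 in 2, came where both replicate 3 libraries stood on one side. The other split of that kind gave 7. This points to a structure of the samples other than the groups.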
